A study of Mus musculus with 6 samples.

How the data were processed

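Gene expression was measured in the colon epithelium of mice fed a standard diet or a diet with 0.4% ursodeoxycholic acid (UDCA), a hydrophilic bile acid that is also used as a drug. Per the series' design text, RNA of 2 animals was combined in each pool, which gives 3 pools of 6 control animals and 3 pools of 6 UDCA animals, and each pool was hybridised to 1 array. The same text also counts 6 samples per group, while it names 3, and the labels carry a cell line tag, IEC-6 (a rat intestinal line), beside the mouse colon epithelium. The 6 arrays were taken as the tissue pools that titles, source and organism name.

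Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled cRNA was made from 3 µg for Affymetrix arrays. The deposited value table gives 1 signal intensity per probe set on a linear scale, from 0 to 12401, for 22690 probe sets, 64 of them Affymetrix controls. The submitters' processing notes name GCOS, the Affymetrix software that summarises probe pairs into a signal; its version, scaling target and detection calls are not given in the sources used here. Trimmed means (2% off each end) were 238, 279 and 308 on the control arrays and 288, 334 and 264 on the UDCA arrays, so the deposited intensity values had not been brought to 1 common level. Medians were 67.4, 75.1 and 84.0 on the control arrays and 73.0, 87.3 and 68.2 on the UDCA arrays. The authors also deposited a table of group averages, medians, spreads and signed folds, whose fold columns are taken as a score because their formula had to be worked out from the values.

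Tests used limma 3.58.1 in R 4.3.3 on log2(intensity + 16), with no further scaling, on the 11313 probe sets in the upper 50% by mean log2 value over the 6 arrays, which begins at a signal of about 75.8. Folds on this scale understate the change of dim genes. UDCA minus control was fitted with lmFit and eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Probe sets were named from the platform annotation table: 20393 had 1 gene symbol, 691 had several and were left unnamed, and 1606 were not listed and are unnamed here. Each gene was represented by its brightest probe set, which gave 6768 genes, and called genes with several probe sets (10 genes) had no probe set of opposite sign. Genes of the fixed list that carry no name in that table were not analysed here.

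Before the data were examined, the design, 37 gene lists, the alternatives and the rule for named genes were fixed. The rule takes, among genes past the threshold whose 3 arrays of one group all lie above the 3 of the other, the 12 with the largest log2 fold change in each direction. Where fewer pass, the genes with the smallest p and groups that do not overlap fill the places and are given as values. Symbols of clones and predicted genes are passed over for naming but counted. In each list the up to 4 measured members with the smallest p are named, and a fixed set of bile acid, sterol, crypt and control genes is given whatever its values. Any other gene named was chosen after its values were seen. Lists with at least 5 members above the filter (23 lists) were tested with camera at a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over lists; camera with an estimated correlation and fry were run beside it. A chaperone list, symbol families and the demand for groups that do not overlap were added after the data had been seen.

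The fit was tested on simulated data for UDCA against control, with 200 changed probe sets among 11313 in each of 20 simulations built on the real means and spreads. With the level differences of the real arrays left in, as in the test used here, 92.9% of changes of 1 log2 unit and 99.8% of changes of 2 were called, with 50.4 unchanged probe sets called per simulation, 20.7% of all calls. After median centring of the simulated arrays these were 80.1%, 97.8% and 8.5, 4.56% of all calls. The share of false calls depends on the planted changes and is no estimate for the real counts. In these simulations the adjusted p-values on the deposited scale let through more false calls than their threshold of 0.05. This design was kept as fixed, with the centred results given beside it. The list test called the shifted list of 30 genes in all 20 simulations, and none of 440 unshifted lists of independent genes. The lists that passed in the data had estimated inter-gene correlations of 0.35 to 0.86. The simulations therefore do not show how often the test errs on such lists.

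Alternatives were quantile normalization, centring each array on its median, pseudocounts of 1 and 64, no filter, the upper 25% by mean, eBayes without trend or with robust estimation, array weights, the pool number as a block, each array left out in turn, a threshold of 0.1, the mean of a gene's probe sets, and the other list tests. The number of arrays limits the precision, and the replicates are pools of different animals. On the deposited scale a gene's variance came mostly from the trend over all genes (53.3 prior against 4 residual degrees of freedom). A gene's p-value there does not measure its own spread between pools. The SE of Retnlb, for example, was 0.43 as deposited and 0.82 after centring. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.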

Results

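Colon epithelium of mice on a standard diet and of mice fed 0.4% UDCA was profiled on Affymetrix arrays, with 3 arrays per group and RNA of 2 animals pooled for each. The question the design poses is which transcripts differ in level under dietary UDCA. Car1, which encodes a carbonic anhydrase of colonocytes, and Actb, which is expressed in most cell types, had mean control signals of 6696 ± 384 and 7342 ± 350 (SD, n = 3). The median named marker had a mean signal of 9.07 for T and NK cells, 9.32 for B and plasma cells, 14.1 for fibroblasts, 16.4 for endothelium, 17.0 for myeloid cells, 18.4 for pancreatic acinar cells and 20.9 for smooth muscle. Single markers of these lists were bright, with control means of 5758 for Sycn, 3644 for Cela1, 2721 for Ctss, 1682 for Sdc1 and 1285 for Tpm1. Xist was bright on all arrays and Y-linked probe sets reached at most 14.3 on any array, so all 6 pools had the transcripts of female animals. The ratio of 3' to 5' Actb control signal was 1.15 to 1.25 over the arrays.

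Among genes that were higher in the UDCA pools, Slpi, which encodes a secreted inhibitor of leukocyte proteases, had a mean signal of 212 ± 90.1 in control pools and 1247 ± 504 in UDCA pools (SD, n = 3), a log2 fold change of 2.48 (SE 0.26; limma adjusted p = 2.85e-08). Apoc2, the activator of lipoprotein lipase, rose from 93.6 ± 4.27 to 322.8 ± 86.6, a log2 fold change of 1.60 (SE 0.20; limma adjusted p = 3.43e-06). Retnlb, a goblet cell protein with antibacterial activity, had the largest log2 fold change among genes with separate groups, 2.62 (SE 0.43; limma adjusted p = 3.15e-04), but its control signals spread from 3.3 to 261.3. The carboxylesterase gene Ces2e rose by 1.48, the ileal bile acid binding protein gene Fabp6 by 1.28, the proglucagon gene Gcg by 1.17 and the L-cell peptide gene Insl5 by 0.92 on the log2 scale. Scd1, a fatty acid desaturase, rose by 1.05, Creld2, an endoplasmic reticulum chaperone factor, by 1.05, Fabp5 by 0.99, Ahsa2, a co-chaperone of HSP90, by 0.91 and the gap junction gene Gja1 by 0.88. The adjusted p-values of these 9 genes lay between 8.74e-04 and 0.028 in limma. Some groups were barely apart as deposited. Scd1 had signals of 1422.3 in control pool 5+6 and 1422.5 in UDCA pool 5+6, and Fabp6 had 245.6 and 250.0 there.

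Among genes that were lower, Fxyd4, a regulator of the sodium pump in colon and kidney, had a mean signal of 2863 ± 1323 in control pools and 875 ± 34.8 in UDCA pools, a log2 fold change of -1.56 (SE 0.24; limma adjusted p = 1.23e-04). The interferon-induced GTPase genes Gbp2 and Gbp7 fell by 1.53 and 1.37, and Trim30a, also interferon-induced, fell by 1.11 on the log2 scale. Rdx, which links membrane proteins to actin, fell by 0.999, the deiodinase gene Dio1 by 0.93, the sulfotransferase gene Sult1c2 by 0.91, the protease gene Adamts15 by 0.89 and Bex1 by 0.84, with limma adjusted p-values up to 0.040. Samhd1, Plpp3 and Cirbp had log2 fold changes of -0.79, -0.81 and -0.75 with groups that did not overlap, and did not pass (limma adjusted p = 0.058 for each).

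**Figure D1:**
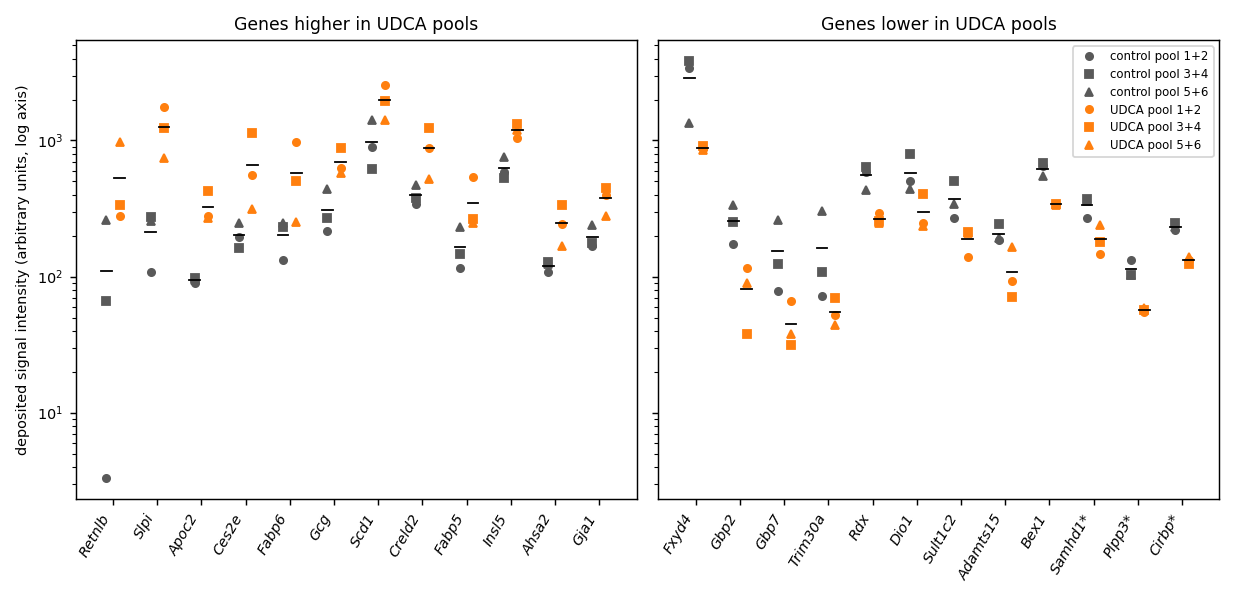
Deposited signal intensity (log axis) of the named genes in each pool, with grey symbols for control pools, orange symbols for UDCA pools and black bars for group means. Slpi, Apoc2 and Fxyd4 show groups that do not overlap, and the genes with an asterisk (Samhd1, Plpp3, Cirbp) did not pass the threshold.

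In all, 44 of 6768 genes passed, 30 higher and 14 lower, and 78 of 11313 probe sets, 51 higher and 27 lower. Of the 44 genes, 22 had groups that did not overlap; over all genes this share was 7.64%, where chance gives 10%. The median log2 fold change of all genes was 0.08. The threshold did not hold its rate in simulated data with the level differences of these arrays. There 50.4 unchanged probe sets were called per simulation, 20.7% of all calls, against 8.5 and 4.56% after centring. That share depends on the 200 planted changes, so the false share of the real counts is not known and can be larger. An exact permutation test of 3 against 3 arrays cannot go below p = 0.1. With the arrays brought to 1 level, by centring or by quantile normalization, 1 gene passed, Apoc2 (limma adjusted p = 0.020 and 0.014), although centring moved every log2 fold change alike by -0.07. After centring the share of genes with separate groups was 20.8%, and 1012 genes had an unadjusted p under 0.05 (974 after quantile normalization). The count was 4 genes without control pool 1+2, 23 without UDCA pool 3+4, 168 without control pool 5+6 and 153 without UDCA pool 5+6. With no filter 0 of 12393 genes passed in limma, while 713 had an unadjusted p under 0.05. Of the 30 genes named in the text that passed, 26 did not without control pool 1+2, 17 without UDCA pool 3+4, 11 without UDCA pool 1+2 and 8 without control pool 3+4. On the deposited scale Apoc2, Slpi and Gbp2 passed whichever single array was left out, and Gbp7 passed except without UDCA pool 3+4 (limma adjusted p = 0.064). After centring 0 genes passed in limma without control pool 1+2, control pool 3+4, UDCA pool 1+2 or UDCA pool 3+4 (504, 650, 599 and 720 at an unadjusted p under 0.05), so the call of Apoc2 was lost there, and 32 passed without control pool 5+6 and 8 without UDCA pool 5+6.

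The interferon response list had the smallest adjusted p in camera on the deposited scale with all arrays. Of its 28 members above the filter, 26 had a negative log2 fold change, with a median of -0.58, and 2 fell, Gbp2 and Trim30a, while 0 rose. Adjusted over the list alone, 10 fell. Parp14 and Irf1, the interferon regulatory factor, had log2 fold changes of -0.77 and -0.64 without passing over all genes. The list passed in camera (adjusted p = 1.82e-20) and not with an estimated correlation (adjusted p = 0.899 with an estimated correlation). Control pool 5+6 stood apart in these genes: after centring, 13 members were there more than 1 log2 unit above the mean of the other control pools, among them Ifit1, Rsad2, Cxcl10 and Oasl2. Without that pool the list still passed in camera at the preset correlation (adjusted p = 0.00386 as deposited and 0.0244 after centring). Its median after centring moved from -0.65 to -0.10, and Trim30a did not pass as deposited (limma adjusted p = 0.227).

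**Figure D2:**
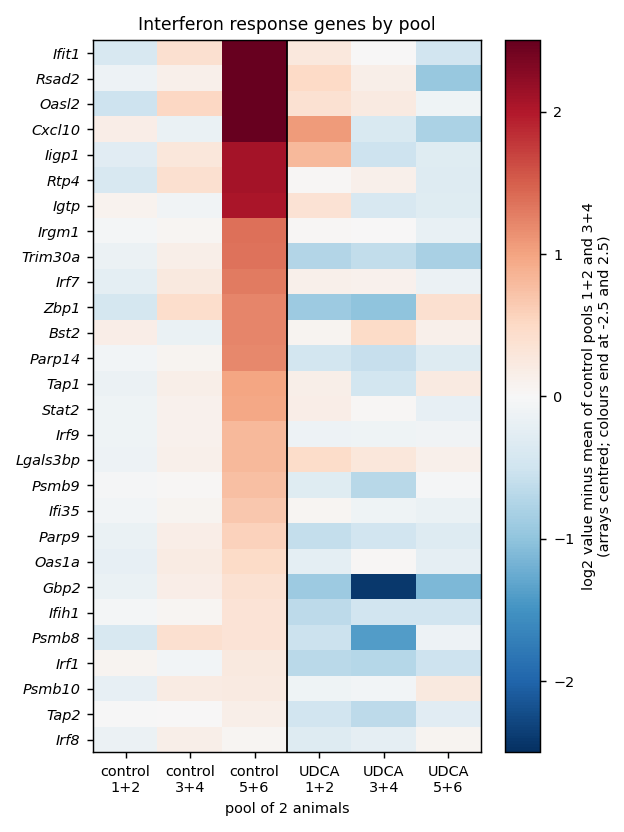
Log2 value of each interferon response gene in each pool minus the mean of control pools 1+2 and 3+4, after each array was centred on its median, with colours from blue (lower) to red (higher). The 13 members that are high in control pool 5+6 stand at the top, and Gbp2, Ifih1, Irf1 and Tap2 are lower in all 3 UDCA pools than in all 3 control pools.

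In the small intestine enterocyte list 3 of 9 measured members rose, Apoc2, Fabp6 and Fabp2, with 4 adjusted over the list alone and a median log2 fold change of 0.48. Apob, the fourth named member, had 0.67 without passing. Fabp2, with a log2 fold change of 1.52 (SE 0.36), had a signal of 800.1 ± 889 in control pools, since pool 5+6 lay with the UDCA pools. The list passed in camera (adjusted p = 8.92e-04; adjusted p = 0.899 with an estimated correlation), and after centring or quantile normalization it did not (adjusted p = 0.144 and 0.152), nor with no filter (0.170) or with array weights (0.502). Among enteroendocrine genes, Gcg and Insl5 rose and 0 of 8 fell over all genes, with 3 that rose and 2 that fell adjusted over the list alone; Chga and Tac1 had log2 fold changes of -0.51 and -0.63. That list did not pass in camera (adjusted p = 0.217).

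Bile acid receptors and transporters had a median log2 fold change of -0.14 over 10 measured members, of which 1 rose, Fabp6, and 0 fell; adjusted over the list alone, 1 rose and 3 fell. Slco2a1, Cyp27a1 and Klb had log2 fold changes of -0.73, -0.70 and -0.72. The bile acid receptor gene Nr1h4 had 0.14 (SE 0.21) and the export pump gene Abcc3 0.12 (SE 0.22), both with overlapping groups. Nr0b2, Fgf15, Slc51a, Abcc2, Cyp3a11 and Ptgs2 lay below the filter, with mean signals of at most 27.6 in either group. The list passed in camera in the lower direction (adjusted p = 0.021; adjusted p = 0.899 with an estimated correlation), and did not after centring (adjusted p = 0.126) or quantile normalization (0.152), nor with no filter (0.170) or with array weights (0.112), nor without control pool 1+2 (0.065), control pool 3+4 (0.348) or UDCA pool 5+6 (0.309).

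Genes of protein folding, respiration and redox defence lay slightly higher in the UDCA pools as groups. In the unfolded protein response list, 26 of 31 members had a positive log2 fold change, with a median of 0.27; 1 rose, Creld2, and 4 rose adjusted over the list alone. Hspa5, Manf and Sdf2l1, factors of protein folding in the endoplasmic reticulum, had 0.58, 0.64 and 0.69 without passing. Of 49 respiratory chain genes 48 had a positive log2 fold change, with a median of 0.22, and 0 passed singly in limma, with 4 at an unadjusted p under 0.05; Uqcrh, Ndufs1, Ndufs3 and Ndufa4 had 0.48, 0.46, 0.42 and 0.42. The NRF2 target list had a median of 0.19 over 26 members and 0 that passed singly in limma, with 3 at an unadjusted p under 0.05. Srxn1, Mt2, Mt1 and Sod2 had 0.69, 0.98, 0.63 and 0.35, each with overlapping groups. UDCA pool 5+6 had the lowest signal of all 6 arrays for Mt2 (619) and Mt1 (2060). In camera these 3 lists passed with adjusted p-values of 1.60e-04, 2.57e-05 and 0.00949 (adjusted p = 0.899 with an estimated correlation for each). The NRF2 target list did not pass without control pool 1+2 (0.056), without UDCA pool 1+2 (0.069) or after quantile normalization (0.152).

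The cell cycle and immediate early lists had medians slightly below 0. The cell cycle list had a median log2 fold change of -0.12 over 43 members, of which 16 were positive (11 after centring and 11 after quantile normalization). Replication genes went both ways. Mcm2, Mcm3, Mcm4, Mcm5, Cdc45, Cdt1 and Fen1 were positive on all these scales, while Mcm6, Mcm10, Gins1 and Lig1 were negative on all. Pcna, Rrm1 and Dut were negative after either scaling, and Mcm7 after quantile normalization. Of the 43 members 0 passed singly in limma and 3 had an unadjusted p under 0.05, and Mki67, Nusap1 and Top2a had -0.44, -0.54 and -0.36 while Rrm2 had 0.50. The immediate early list had a median of -0.06 over 29 members, of which 9 were positive, with 0 that passed over all genes in limma, 1 that fell adjusted over the list alone and 3 at an unadjusted p under 0.05; Egr2, Nr4a1 and Erbb3 had -0.84, -0.70 and -0.37 and Ier3 had 0.66. Both lists passed in camera (adjusted p = 0.00478 each; adjusted p = 0.899 with an estimated correlation). The cell cycle list did not pass without control pool 1+2 (0.566), control pool 5+6 (0.121) or UDCA pool 3+4 (0.450), and with array weights its direction turned (0.00994). The immediate early list did not pass with no filter (0.164), with array weights (0.964) or without control pool 3+4 (0.057), and without UDCA pool 5+6 its direction turned (0.925).

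The other tested lists did not pass in camera (smallest adjusted p = 0.072, for electrolyte transport). Of 43 surface colonocyte genes 1 rose, Tmigd1, with overlapping groups and a log2 fold change of 2.80. Adjusted over the list alone, 4 rose and 1 fell. Cldn8, Dpep1 and Cdx2 had -0.78, 0.90 and 1.08, also with overlapping groups. Control pool 5+6 had a Cdx2 signal of 795.6, above every UDCA pool, and a Dpep1 signal of 1638, above UDCA pools 1+2 and 5+6. Of 20 goblet cell genes 1 rose, Retnlb, while Ccl9, Capn9 and Spink4 had 0.74, 0.40 and 0.31. In the antimicrobial list, 1 of 13 rose, Retnlb, with 2 that rose and 1 that fell adjusted over the list alone, and Pla2g2a, Il18 and Reg4 had 0.86, -0.52 and 0.42. Its median was -0.02, while its mean was 0.27 and its camera direction was up, which turned to down after centring. Of 17 Wnt target and crypt base genes 0 passed over all genes and 1 fell adjusted over the list alone, with 4 at an unadjusted p under 0.05; Rnf43, Prom1, Sox9 and the stem cell marker Lgr5 had -0.68, 0.55, -0.46 and -0.42. That list had a median above 0, 0.04, while its mean was -0.04 and its camera direction was down. Of 31 electrolyte transport genes 2 fell, Fxyd4 and Slc4a4, and 3 rose and 3 fell adjusted over the list alone. S100g and Aqp4 had 1.79 and 0.89, and both, like Slc4a4, had overlapping groups. S100g had a signal of 1613 in UDCA pool 3+4 but 29.7 in UDCA pool 5+6, the lowest of the 6 arrays. For Aqp4 control pool 5+6 (4183) lay above every UDCA pool. Of 47 xenobiotic genes 2 rose, Ces2e and Cyp2c65, and 1 fell, Sult1c2, also adjusted over the list alone; Cyp2d26 had 0.70. Of 15 fatty acid synthesis and sterol efflux genes 1 rose, Scd1, with 2 that rose and 2 that fell adjusted over the list alone; Abcg5, Fads1 and Mylip had -0.82, 0.65 and -0.56.

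No gene passed in the lists for cholesterol synthesis (21 genes), fatty acid oxidation (24), NF-kB targets and cytokines (14), apoptosis (34), clock genes (15) and ribosomal proteins (38), over all genes or adjusted over the list alone. In limma 1, 0, 2, 3, 0 and 0 of them had an unadjusted p under 0.05. Fdps, Lss, Mvd and Nsdhl of the sterol pathway had log2 fold changes of 0.49, 0.40, 0.30 and 0.29, and Hmgcs1 had 0.07 (-0.01 after centring and -0.02 after quantile normalization). Cpt2, Ppargc1a, Acaa2 and Etfb had 0.43, -0.44, 0.34 and 0.31. Cxcl1, Cxcl5, Birc3 and Nfkbiz had 0.63, -0.54, -0.42 and -0.38, and Casp6, Cycs and Ccng1 had 0.53, 0.37 and 0.43. Dbp, Npas2, Cry1 and Arntl had 0.83, -0.35, 0.34 and -0.32, and Rpl27a, Rps18, Rps14 and Rpl35 had 0.36, 0.20, 0.18 and 0.19. In the colon position list (9 genes) 1 rose, Insl5, and Hoxd13, Mep1a and B3galt5 had -0.54, -0.35 and 0.24. The apoptosis, clock and colon position lists had medians of 0.01, 0.05 and 0.04 and means above 0, while their camera direction was down. The medians of these lists and of the Wnt, surface colonocyte and goblet cell lists lay below 0 after centring.

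The remaining lists of cell types had too few members above the filter to be tested. None of 25 fibroblast, 16 endothelial and 17 neuron and glia markers lay above it. MHC class II genes, which antigen-presenting cells and some epithelial cells express, had 4 measured members, of which 2 rose, Cd74 (log2 fold change 1.38, SE 0.28) and H2-Aa (1.45, SE 0.30), both with overlapping groups; H2-Ab1 and Ctss had 0.46 and -0.25. Among myeloid markers Kit and Cd14 had -0.22 and -0.13, and Zap70 of the T cell list and Sdc1 of the plasma cell list had -0.07 and 0.27. Smooth muscle markers Mylk, Tpm2, Tpm1 and Csrp1 had -0.21, 0.22, 0.16 and -0.05, and adipocyte markers Lpl, Pparg and Pnpla2 had -0.25, 0.08 and 0.05, the last -0.03 after centring and -0.04 after quantile normalization. The pancreatic markers Sycn, Cela1, Zg16 and Clps had -0.42, -0.34, 0.14 and -0.08, the tuft cell genes Plcg2 and Krt18 had 0.12 and 0.02 (Krt18 -0.06 after centring and -0.09 after quantile normalization), and the erythroid marker Bpgm had 0.12. Of the control genes Actb had 0.17 and Car1 0.09 (0.01 after centring and -0.02 after quantile normalization), and Xist had -0.27.

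The folds in the authors' deposited table do not compare UDCA with control pools. Its average for N equals the mean of all 6 arrays in 22690 of 22690 probe sets (within 0.0051) and the mean of the 3 control arrays in 55. The fold equals the UDCA mean against that mean of all 6 arrays, with the divisor raised to 20, in 22685 probe sets (within 0.011). Folds of higher probe sets therefore cannot exceed 2, and the largest in the authors' deposited table is 1.88. The authors' deposited table has 38 probe sets that are higher by a fold of 1.5 or more and 76 that are lower, whereas the same formula with the control mean gives 397 and 383. Slpi is listed at 1.71 in the authors' deposited table, against 5.87 by the control mean, and Fxyd4 at -2.14 against -3.27. Between the authors' folds and the log2 fold changes of the limma fit Spearman's rho was 0.992 across 6768 genes, which are not independent replicates.

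**Figure D3:**
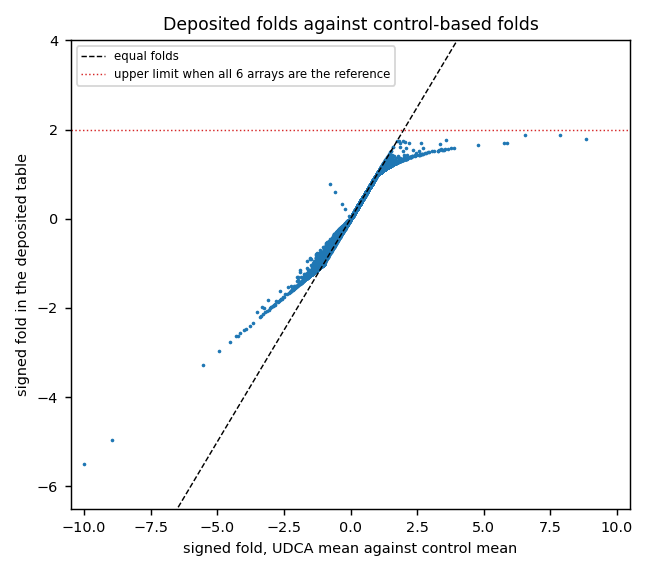
Signed fold in the authors' deposited table (y axis) against the signed fold of the UDCA mean to the control mean by the same formula (x axis), 1 point per probe set, with a dashed line for equal folds and a dotted line at 2. The deposited folds of higher probe sets level off below 2, while the control-based folds reach 8.82.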

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

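All tests of explanations in this part were chosen, and the bounds they were read against were set, after the results were seen. A mouse control probe set outside the comparison stood higher in the UDCA pools. The middle-region control of the transferrin receptor gene Tfrc, the receptor for iron uptake, had a mean signal of 54.0 ± 28.4 in control pools and 139.1 ± 79.5 in UDCA pools (SD, n = 3), a ratio of 2.58 with groups that did not overlap. The 3' and 5' controls of the same gene had ratios of 2.16 and 2.57 with overlapping groups. The ordinary probe set of Tfrc rose too (log2 fold change 1.06, SE 0.23; limma adjusted p = 0.013), with overlapping groups because control pool 5+6 had 2506 and UDCA pool 5+6 had 2259. After centring Tfrc had 0.99 (SE 0.26; limma adjusted p = 0.262), and it did not pass without control pool 1+2 (0.484), UDCA pool 1+2 (0.087) or UDCA pool 3+4 (0.117), or with no filter (0.856).

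The interferon response genes were lower in the UDCA pools, and control pool 5+6 is a candidate source of a large part of this: over all 28 members the median log2 fold change after centring was -0.65 with it and -0.10 without it (quartiles -0.47 and -0.03). Whether that pool is the whole source stays open. The highest UDCA pool, 1+2, had a list median 0.096 above that of the lower remaining control pool, 1+2. UDCA pools 3+4 and 5+6 lay below that control pool. Of the 28 members 8 were lower in every UDCA pool than in every control pool, 28.6%, against 8.61% of all genes after centring and 5% by chance. That share does not decide the question, since the members move together (estimated correlation 0.79 as deposited). A high control pool 5+6 by itself also makes such separation easier. Gbp2 had -1.61 after centring with all arrays and -1.48 without control pool 5+6. Fewer leukocytes in the UDCA pools stay open too, since only 5 of 68 markers of T, B and myeloid cells lay above the filter. Their median log2 fold change was -0.20 after centring, and Sdc1 among them had 0.19 with overlapping groups (limma adjusted p = 0.537). Cd74 and H2-Aa, which antigen-presenting and some epithelial cells express, had higher means in UDCA pools, also with overlapping groups. After centring these 2 had 1.31 and 1.38 (limma adjusted p = 0.282 and 0.286). As deposited both passed in limma (0.00654 and 0.00670), but not without control pool 1+2 (0.626 and 0.674). An effect of UDCA on interferon signalling, and an infection or other exposure of the animals in control pool 5+6, stay open and were not tested.

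The 6 arrays can be split into groups of 3 in 10 ways, so no share under 0.05 can be reached. The real split gave 78 probe sets and 44 genes, reached by 1 split each, itself, and the highest of the others gave 45 and 16. For lists the real split gave 8 past the threshold, 2 splits including it gave as many, and the highest other gave 15. After centring the real split gave 1 probe set, as did 1 other (control pools 1+2 and 3+4 with UDCA pool 3+4 against the rest), and 1012 genes at an unadjusted p under 0.05, where the highest of the others gave 718.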

How the results depend on the processing

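Chosen after seeing the data were centring with arrays left out, centring with the other list tests, and the demand for separate groups; the present-call filter was not run because no detection calls were used here, and robust estimation has no list test. The count of 78 probe sets and 44 genes depended on the scaling of the arrays, while log2 fold changes stayed about as large after centring. After quantile normalization 1 probe set and 1 gene passed, and after median centring 1 and 1, all higher; Apoc2 was that gene in both, and its log2 fold change moved from 1.60 (SE 0.20) to 1.53 (SE 0.14). Centring moved Slpi from 2.48 (SE 0.26) to 2.41 (SE 0.32), Fxyd4 from -1.56 (SE 0.24) to -1.63 (SE 0.39) and Gcg from 1.17 (SE 0.23) to 1.10 (SE 0.17), and genes with an unadjusted p under 0.05 rose from 510 to 1012. It lowered the prior degrees of freedom from 53.3 to 4.72, and with them those of each test; what part of the lost calls this explains was not tested. In simulations with 200 planted changes 20.7% of the calls were false with the level differences and 4.56% after centring. These were 50.4 and 8.5 probe sets per simulation. The shares depend on the planted changes and are no estimate for the real counts. With no filter 0 probe sets and 0 genes passed in limma (1207 and 713 at an unadjusted p under 0.05); the cause was not tested. Asking also for separate groups left 38 and 22. Array weights gave 7101 probe sets and 4210 genes, with weights from 0.21 to 45.8 from an estimate that did not converge. Leaving out 1 array gave 5 to 253 probe sets and 4 to 168 genes, and 0 to 45 probe sets and 0 to 32 genes after centring; the lowest counts as deposited came without control pool 1+2 and the highest without control pool 5+6. Pseudocounts of 1 and 64, the upper 25% by mean, no intensity trend, robust estimation and a threshold of 0.1 kept both counts within 1.5 times, and the mean of probe sets that of genes (50), but not all were the same genes: of the 44 genes, 41 and 42 were shared with these pseudocounts, 21 with the upper 25%, 33 with no trend, 27 with robust estimation and 42 with the mean. Genes below the upper 25% could not be shared there. Of the 30 named genes that passed, 15 lay within it, and these 15 kept their call. Of 30 named genes 5 lost their call with no trend and 9 with robust estimation (Cd74, Cyp2c65, Fabp2, Fabp6, H2-Aa, Hsph1, Retnlb, Tmigd1 and Trim30a). The pool number as a block gave 126 probe sets and 62 genes (lists 8); same-numbered pools had deviations correlated at -0.10, 0.16 and 0.05, not every pool correlated best with its own number, and nothing in the labels pairs them.

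Over all 23 tested lists, 8 passed as deposited, 6 after median centring, 5 after quantile normalization and 5 with no filter (35 lists tested). With an estimated correlation or fry 0 passed, as deposited or centred. At an unadjusted p under 0.05 these tests gave 0 lists as deposited. After centring they gave 0 with an estimated correlation and 2 with fry. Leaving out 1 array gave 5 to 11 in camera, and 4 to 8 after centring. Of 30 named genes past the threshold, 29 lost it after either scaling and 30 with no filter, 26 without control pool 1+2 and 17 without UDCA pool 3+4, and none changed sign. Interferon, mitochondrial and unfolded protein lists lost their call only with an estimated correlation or fry (adjusted p up to 0.899). The cell cycle list turned its direction with array weights (adjusted p = 0.00994), and its values without 1 array ran from 4.52e-08 to 0.566; the immediate early list ran from 5.45e-09 without UDCA pool 1+2 to 0.925 without UDCA pool 5+6, where its direction turned, and was 0.164 with no filter and 0.964 with array weights. The cause was not tested.

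The log2 fold changes of 18 named genes, none past the threshold, changed sign in some setting. After quantile normalization these were Car1 -0.015, Hmgcs1 -0.020, Krt18 -0.090 and Pnpla2 -0.042, and after centring, which lowers every log2 fold change alike, Hmgcs1 -0.0050, Krt18 -0.056 and Pnpla2 -0.028. With array weights they were Arntl 1.04, Capn9 -0.46, Dbp -2.94, Npas2 0.55, Plcg2 -0.088, Pnpla2 -0.031, Top2a 0.18, Tpm2 -0.066 and Zap70 0.43. Leaving out 1 array gave ranges of -0.0098 to 0.34 for Abcc3, -0.031 to 0.49 for B3galt5, -0.35 to 0.094 for Clps, -0.27 to 0.16 for Csrp1, -0.071 to 2.38 for Dbp, -0.081 to 0.18 for Hmgcs1, -0.13 to 0.16 for Krt18, -0.55 to 0.087 for Lpl, -0.054 to 0.28 for Plcg2, -0.045 to 0.12 for Pnpla2, -0.27 to 0.44 for Pparg, -0.042 to 0.40 for Tpm2 and -0.21 to 0.12 for Zap70. Other causes were not tested. The filter began at a signal of 75.8, so dimmer genes were tested only with no filter.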

Other observations

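The tests of symbol families, of chaperones and of the pools numbered 3+4 were chosen after the data were seen, while the limma calls of single genes, their leave-outs and the clock list's test between diets were planned. Families of genes were formed by the letters of their symbols, and the 74 families with at least 10 measured genes were tested with camera. Mitochondrial ribosomal proteins lay higher in the UDCA pools, with a positive log2 fold change in 46 of 47 Mrpl genes (median 0.29) and in 27 of 27 Mrps genes (median 0.28), as did 14 of 14 Psmd genes of the proteasome's regulatory particle (median 0.36) and 13 of 13 Timm genes of mitochondrial protein import (median 0.37). Kinesins (Kif, median -0.22 over 14 genes), Trim genes (-0.10 over 23) and Klf transcription factors (-0.17 over 10) lay lower. These 7 families passed on the deposited scale and after centring, where Zfp genes passed too (adjusted p = 0.027), the 7 with adjusted p-values up to 0.00391 there, and with an estimated correlation none of the 74 passed in camera (smallest adjusted p = 0.582 with an estimated correlation). On the deposited scale 1 gene of these families passed singly, Trim30a, and after centring it did not (limma adjusted p = 0.263). After centring 41 of the 47 Mrpl genes were positive. Kif11, Kif20a and Kif23 are also members of the cell cycle list and Trim30a of the interferon list. The Kif and Trim results are therefore not separate from those of these lists. Families were not tested with single arrays left out.

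A list of chaperones and co-chaperones was written after several of them had been seen among the genes that rose. Of 33 measured members 3 rose, Hsph1, Chordc1 and Ahsa2, and 0 fell; after centring these 3 did not pass (adjusted p = 0.262 each), nor without control pool 1+2 (0.484, 0.538 and 0.396) or UDCA pool 3+4 (0.139, 0.223 and 0.200), nor did Chordc1 without UDCA pool 1+2 (0.245). The median log2 fold change was 0.40 as deposited and 0.33 after centring, with 32 members positive and a lower quartile of 0.22. Centring moved every log2 fold change alike by -0.07, so this outcome followed from the deposited values. It shows only that 1 shift per array is smaller than the list's median. A level difference that varies with intensity stays open. A difference held by UDCA pools 1+2 and 3+4 alone stays open: these lay above the control mean by medians of 0.39 and 0.45 and UDCA pool 5+6 by 0.19, while control pool 5+6 lay above the other control pools by 0.13, and UDCA pool 5+6 exceeded the highest control pool by a median of 0.070 (lower quartile -0.065), in 21 of 33 members. The camera p after centring was 1.08e-15, and 0.059 with an estimated correlation, on genes picked in part because they rose. Members differed in size of change. Hspa1a, Hspa1b and Dnajb1 had log2 fold changes of 0.18, 0.20 and 0.07, and 0.11, 0.12 and -0.0049 after centring. Hsph1, Dnaja1, Hspb1, Hsp90aa1 and Bag3 had 1.49, 0.91, 0.47, 0.40 and 0.33 as deposited. An effect of UDCA itself was not tested apart from other differences between the groups.

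Several clock genes were highest in the pools numbered 3+4 of both groups. Dbp, an output gene of the circadian clock, had signals of 34.7, 1061 and 19.9 in control pools 1+2, 3+4 and 5+6, and 112, 560 and 133 in the UDCA pools. Of 15 measured clock genes, 8 were highest in pool 3+4 of both groups after centring (Cry2, Dbp, Nr1d2, Per1, Per2, Tef, Usp2 and Wee1), where 10000 random lists of that size had a median of 2 and a 95th percentile of 4. Arntl and Npas2, which peak at the opposite time of day, were lowest in control pool 3+4 (140.4 and 61.6) but not in UDCA pool 3+4, where Arntl had 201.1 against 148.4 in pool 5+6 and Npas2 had 123.4, the highest of the UDCA pools. A collection of these pools at another time of day is thus a hypothesis that stays open, found and tested on the same arrays. The labels used here give no time of collection, and the clock list did not pass the test between diets (camera adjusted p = 0.255). The log2 fold change of Dbp between diets, 0.83, ranged from -0.07 without control pool 5+6 to 2.38 without control pool 3+4.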
